A study of Mus musculus with 14 samples.

How the data were processed

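Total RNA of 14 primary mouse glioblastomas was measured, 1 tumour per array, on single-colour Illumina mouse bead arrays labelled with biotin. The tumours formed a group of 7 Type 1 and a group of 7 Type 2 tumours and were run in 2 batches, with 3 Type 1 and 4 Type 2 arrays in batch 1 and 4 Type 1 and 3 Type 2 arrays in batch 2. The arrays lay on 5 chips, and each chip held tumours of a single type. A difference between chips can therefore not be told apart from a difference between types. Replicate numbers were given in accession order, name a tumour only and pair nothing.

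Per the file headers, the deposited non-normalized table held an average bead signal intensity and a detection p-value for each of 45281 probes on each array, with no normalization by the authors. BeadStudio is named in the submitters' processing notes, and its version is not given in the sources used here. A second deposited table held log2 values processed by the authors for 38502 probes. The method behind it is not given in the sources used here. Its direction and centring were examined by setting each array's deviations from its batch mean against those of the log2 signals over 4554 bright probes. Each array correlated with itself at r between 0.991 and 0.998, and at most at 0.305 with any other array, so direction followed log2 signal. A correlation does not depend on scale, which was not examined. Array medians of the authors' values lay between 2.67 and 2.69. Probe levels ranged from -23.94 to 29.39 and correlated with mean log2 signal only at r = 0.378 across probes, so the centring of each probe stays unknown and only differences between arrays were used. The median absolute difference between batches was 0.486 in log2 signals and 0.118 in the authors' values. This table served as an alternative.

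Signals were background-corrected with normexp from the detection p-values, given an offset of 16, quantile-normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3. Gene names came from the platform annotation, which can be old, and were matched to a mouse reference gene table (assembly GRCm38.p6) through Entrez identifiers. Of the probes, 32034 had 1 gene symbol, 16 had several and were left out, and 13231 had no gene name here. The reference table held the genes of 31976 probes, and chromosomes were taken from it. A probe was kept if its detection p was under 0.05 on at least 3 arrays, which left 18430 named probes. The probe with the highest mean over the 14 arrays stood for its gene, which gave 11786 genes. Of these genes, 4521 had more than 1 detected probe. Among the named genes, 39 had more than 1 detected probe, and the probes of 0 of them differed in sign.

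The types were compared gene by gene with limma (lmFit and eBayes), with batch as a term and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. Differences are Type 1 minus Type 2 on the log2 scale. For a gene detected on no array of one type, the fold is a bound: the mean of the brighter type over the mean of, per array, the higher of the lowest signal among detected probes and the gene's own. That bound compares the means of these tumours and takes in neither the batch term nor the spread between tumours. The type by batch interaction and the batch term were tested the same way. Gene lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over 31 lists. Of 35 lists, 4 had fewer measured genes. The number of arrays limits the precision of every value. The labels describe separate tumours of mice of the 2 genotypes but give no further animal details used here, so p-values measure the spread between these tumours.

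The sample groups, the main tests, the 35 gene lists, the naming rule and the alternatives in the next paragraph were fixed before the data were examined. The covariates for Xist and fibroblast genes, leaving out 2 tumours high in choroid plexus genes, the pigment, peripheral nerve, fibroblast and imprinted gene lists and some further tests were chosen after seeing the data. The rule named the 12 genes with the largest called difference in each direction that had the same sign in both batches, leaving out predicted and unnamed transcripts. It also named genes of the design, among them Nes, Cspg4, Trp53 and Nf1, the 4 genes with the lowest p of each list past its test, the top called gene of other lists, and genes in counts of 5 or fewer. This gave 76 genes before the last part, and 14 predicted or unnamed transcripts were passed over. Trp53 was not analysed here, and part of the design is not reported here.

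Alternatives covered the batch term, chip as a random block (consensus correlation 0.0149), each batch alone, background correction, scaling, the authors' values, detection filters, probe averaging, array weights, the variance prior, a covariate for normal brain, list tests, thresholds and leaving out each tumour. The model was tested on simulated data with the means, batch effects and spreads of the 11786 genes of this comparison and 200 changed genes, over 20 simulations. Of the genes changed 4-fold, 92.5% were recovered, against 62.6% of those changed 2-fold and 9.78% of those changed 1.5-fold. Of all calls, 4.88% were false. Genes were simulated as independent, so list tests were not put to their hardest case there.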

Results

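Glioblastomas were induced in adult mice by a single oral dose of tamoxifen, 10 mg per 20 g body weight, at 6 to 8 weeks of age. Tamoxifen activated a Cre recombinase driven by the Nestin promoter (Type 1) or the NG2 promoter (Type 2). NG2 is the proteoglycan encoded by Cspg4. In both types the targets of Cre included floxed Trp53 (both alleles), floxed Nf1 (1 allele) and a tdTomato reporter. The question was how tumours started from the 2 drivers differ in expression. Each of the 14 arrays measured the total RNA of 1 tumour, with 7 tumours per type in 2 batches. Between 19299 and 20868 probes were detected per array, with a mean of 20298 ± 574 (SD, n = 7) in Type 1 and 20354 ± 451 (SD, n = 7) in Type 2. Values are normalized log2 signals from bead arrays, and the number of arrays limits their precision.

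Type 1 tumours had far more RNA for the growth factor receptor Egfr, at 11.72 ± 1.15 (SD, n = 7) against 7.79 ± 0.85 (SD, n = 7) in Type 2. The difference was 3.92 ± 0.51 (SE) on the log2 scale, or 15.1-fold, with a limma adjusted p of 0.00213, and it was 4.34 in batch 1 and 3.49 in batch 2. Glra2, a glycine receptor subunit detected on 7 of 7 Type 1 and 2 of 7 Type 2 arrays, differed by 3.35 ± 0.54 (SE), and Gria1, an AMPA receptor subunit, by 2.77. Cbln4, which encodes a secreted synaptic protein, was detected on 7 of 7 Type 1 arrays and 0 of 7 Type 2 arrays. Its mean was at least 4.86-fold higher in Type 1. Usp29, which lies beside the imprinted gene Peg3 on chromosome 7, had the lowest adjusted p, 0.000125 by limma, with a difference of 2.89 ± 0.25 (SE), and was detected on 2 of 7 Type 2 arrays. The other genes of this group were Col26a1 (3.33), Kcne1l (3.12), the zinc transporter gene Slc39a12 (2.90), the long non-coding RNA Miat (2.76), Fbll1 (2.71), the neuronal splicing factor gene Rbfox3 (2.65) and Agt, which encodes angiotensinogen (2.57). Glra2, Kcne1l, Slc39a12, Miat, Fbll1 and Agt were not called in batch 1 alone, where their differences were 4.17, 3.44, 3.71, 3.03, 3.31 and 3.30. Col26a1, Kcne1l, Slc39a12, Gria1, Rbfox3 and Agt were not called in batch 2 alone, where their differences were 1.63, 2.80, 2.08, 1.14, 1.31 and 1.85. Without Type 1 replicate 2, Col26a1 (adjusted p = 0.0567) and Rbfox3 (0.0542) lost their call. With a fibroblast covariate, chosen after seeing the data, Glra2, Col26a1, Slc39a12, Miat, Fbll1 and Rbfox3 lost it, and without the 2 tumours highest in choroid plexus genes Egfr, Glra2, Cbln4 and Usp29 kept it.

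Type 2 tumours had more RNA for Dct, a melanin synthesis enzyme, at 9.61 ± 1.24 (SD, n = 7) against 5.22 ± 0.58 (SD, n = 7) in Type 1, a difference of -4.40 ± 0.49 (SE; limma adjusted p = 0.000636). It was detected on 2 of 7 Type 1 arrays, Dhh on 3 and Pmel on 5. Pmel, a melanosome protein, differed by -3.84 ± 0.53 (SE). Dhh, a hedgehog ligand made by Schwann cells, differed by -4.20 ± 0.70 (SE), and the adhesion molecule gene Mcam by -3.09 ± 0.33 (SE). Acan, which encodes a matrix proteoglycan, was detected on 0 of 7 Type 1 arrays and was at least 5.40-fold higher in Type 2. The remaining genes were the protease gene Klk8 (-3.54), the transcription factor gene Gata6 (-3.07), the matrix protein gene Mgp (-2.96), Mrgprf (-2.85), Eya1 (-2.84), Angptl1 (-2.84) and the neurotrophic factor gene Gdnf (-2.83). In batch 1 alone Dct and Mcam kept their call and the other 10 genes lost it, and Dhh, Gata6, Mgp and Gdnf also lost it in batch 2 alone. Of the 14 tumours left out in turn, 11 ended the call of Gata6, 7 that of Eya1 and 1 that of Acan (Type 1 replicate 2, adjusted p = 0.0552). Without the 2 tumours highest in choroid plexus genes, Acan, Angptl1, Eya1, Gata6 and Gdnf lost it. Of 5 measured fibroblast genes, a list chosen after seeing the data, Lum (-2.47) and Col1a1 (at least 2.28-fold) were higher in Type 2 and 3 did not pass, with a median of -0.68. With the mean of these genes as a covariate, Dct (-3.17 ± 0.37, SE) and Mcam (-2.97 ± 0.44, SE) kept their call, and the others lost it, among them Pmel (-3.30 ± 0.67, SE) and Dhh (-3.22 ± 0.82, SE).

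**Figure D1:**
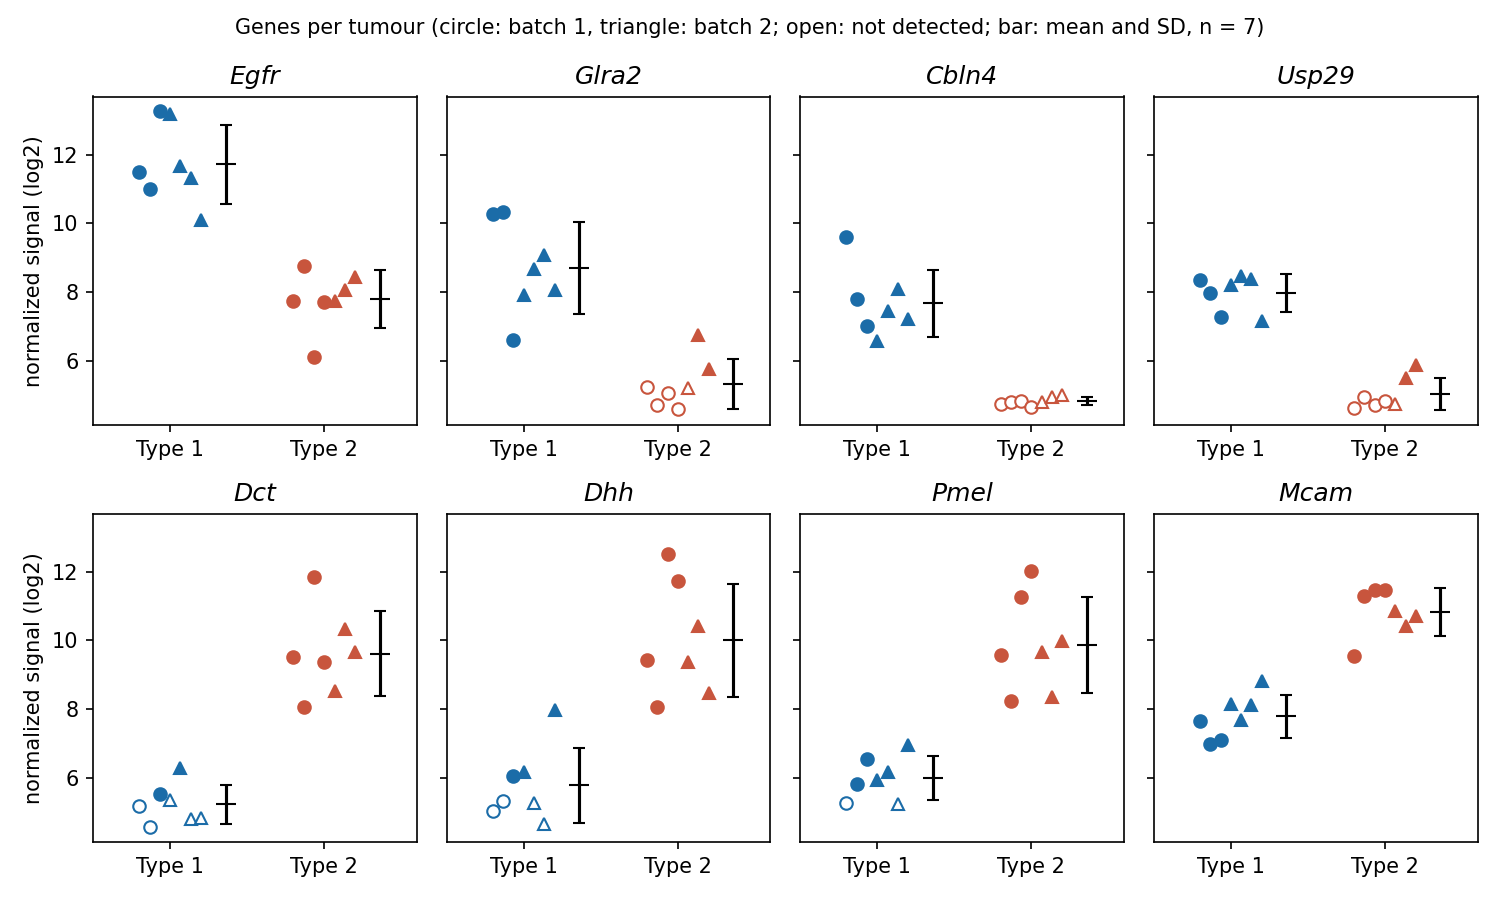
Normalized log2 signal of 8 genes in each of the 14 tumours (vertical axis) by tumour type (horizontal axis), with filled symbols for detected and open symbols for undetected probes, and bars for the mean and SD of 7 tumours. Egfr lay at 11.72 in Type 1 and 7.79 in Type 2 on average, and Dct at 5.22 and 9.61.

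The genes whose promoters drove Cre did not pass the test. Nes, which encodes nestin, differed by 0.57 (95% confidence interval -0.08 to 1.22, limma adjusted p = 0.291). Cspg4 differed by -0.90 (95% confidence interval -1.73 to -0.075, limma adjusted p = 0.190, unadjusted p = 0.0346). The interval of Cspg4, which is not adjusted over genes, lay below 0. Within batches Nes differed by -0.03 in batch 1 and 1.17 in batch 2, and Cspg4 by -1.07 and -0.73. The Nf1 probe was detected on 2 of 14 arrays, which is too few to be tested. It does not check the deletion. Trp53 was not analysed here.

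In all, 547 of 11786 genes differed between the types, 274 higher in Type 1 and 273 higher in Type 2 (limma, adjusted p under 0.05). Of these, 325 differed by at least 2-fold and 67 had an adjusted p under 0.01. All 547 had the same sign in both batches, which calling on the difference over both batches favours. Of all genes tested, 54.7% did. With chip as a random block, 465 genes were called, and Gata6, Elavl4, Col1a1, Col6a1, Hoxa2 and Stat3 lost their call. Since no chip held both types, this setting cannot remove a chip effect from the type difference. The count depended on single tumours. Leaving out Type 1 replicate 2 gave 195 genes, Type 1 replicate 5 gave 267, and Type 1 replicate 1 gave 308. Leaving out Type 2 replicates 3, 4, 5, 6 and 7 in turn gave 278, 330, 326, 344 and 347. Without the 2 tumours highest in choroid plexus genes, which was chosen after seeing the data, 106 genes were called, 99 of them among the 547. With the fibroblast covariate, also chosen then, 47 were called, 34 higher in Type 1 and 13 in Type 2, and type and batch explained 48.1% of that covariate.

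Each batch alone called fewer genes, 166 in batch 1 (125 higher in Type 1, 41 higher in Type 2) and 123 in batch 2 (37 and 86). The 10 genes called in both were Egfr, Usp29, Peg3, Cbln4, Celsr3 and Entpd6, higher in Type 1, and Dct, Mcam, Aoc3 and S100a3, higher in Type 2, against 1.73 expected of independent lists. Peg3 differed by 2.32 ± 0.23 (SE), and in the batches by 2.76 and 1.88. Across all genes, which are not independent replicates, the differences of the batches correlated at Pearson r = 0.261 and Spearman rho = 0.173, and 54.7% had the same sign. Among genes called in batch 1 the correlation was 0.552, and among those called in batch 2 it was 0.758. With all tumours and the main settings, no gene passed the test of a type by batch interaction (limma, 0 genes at adjusted p under 0.05, 1931 at unadjusted p under 0.05), but 36 did without Type 1 replicate 2, 8 without Type 1 replicate 7, 2 without Type 2 replicate 6, and 1 each without Type 1 replicate 5, Type 2 replicate 1 or Type 2 replicate 3. With no detection filter 11 passed, with a stricter filter 5, with no background correction 2 and with the authors' values 1.

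**Figure D2:**
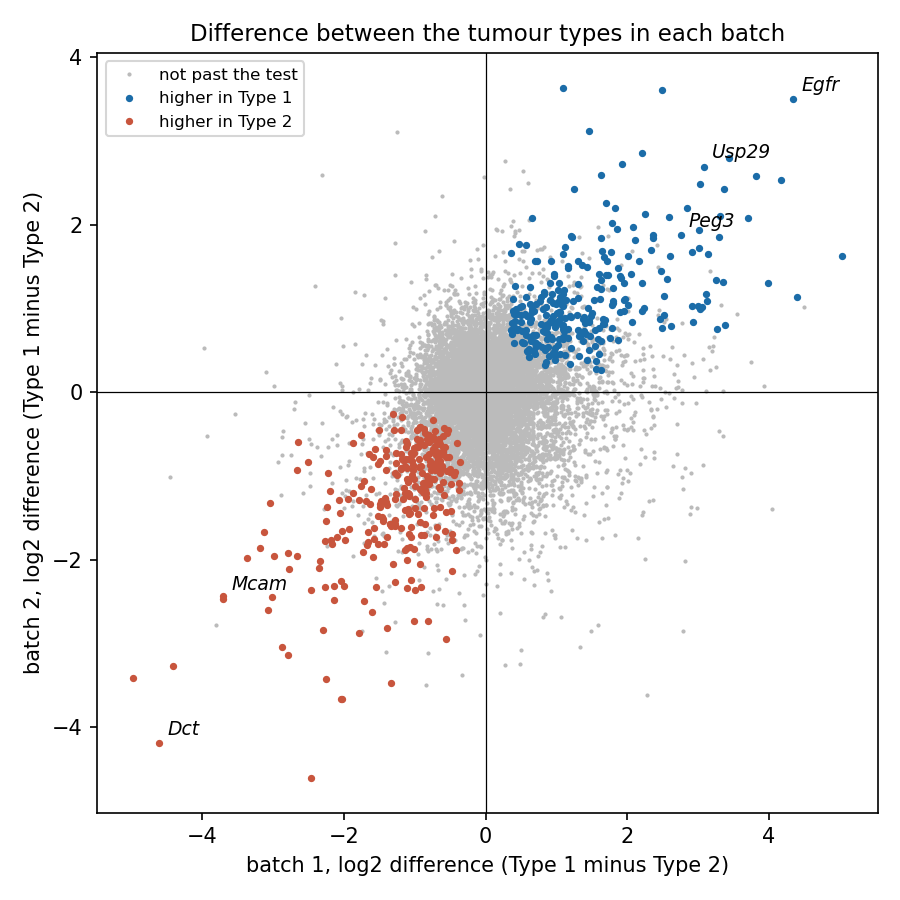
Log2 difference between the types (Type 1 minus Type 2) of each gene in batch 1 (horizontal axis) and batch 2 (vertical axis), with the 274 genes higher in Type 1 in blue, the 273 higher in Type 2 in red and the rest in grey. Egfr, Usp29, Peg3, Dct and Mcam lie far from 0 in both batches, and r over all genes was 0.261.

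Among the gene lists, 6 were higher in Type 1 by camera with a preset correlation. Of 16 measured astrocyte genes, 4 were higher in Type 1 (Aqp4, Slc1a2, Sox9 and Slc4a4), 1 was higher in Type 2 (S100b) and 11 did not pass, with a median difference of 0.92 (camera adjusted p = 1.015e-05; adjusted p = 0.187 with an estimated correlation). The water channel gene Aqp4 differed by 2.12 ± 0.48 (SE), and Sox9, a glial transcription factor gene, by 1.67 ± 0.27 (SE). Adjusted over the list alone, 6 astrocyte genes were higher in Type 1 and 1 in Type 2. Of 11 neuroblast genes, 4 were higher in Type 1 (Dcx 2.33, Igfbpl1 2.12, Elavl3 1.64 and Elavl4 1.19), with a median of 1.06 (camera adjusted p = 0.00156, and 0.0979 with an estimated correlation) and 5 genes adjusted over the list alone. That median was 0.69 without Type 2 replicate 5 and 1.18 without Type 1 replicate 7. Of the 14 tumours left out in turn, 12 ended the call of Igfbpl1, 12 that of Elavl4, 9 that of Elavl3 and 5 that of Dcx. Of 17 neural stem and progenitor genes, Egfr, Id1 and Lhx2 were higher in Type 1 and 14 did not pass (median 0.51; adjusted p = 0.0016; adjusted p = 0.161 with an estimated correlation). For 13 genes of the human glioblastoma classical list the median was 0.57 (camera adjusted p = 0.00597, and 0.152 with an estimated correlation), and Egfr, Sox9 and Elovl2 were higher in Type 1. The classical median was 0.37 without Type 1 replicate 3 and 0.73 without Type 1 replicate 2. Forebrain patterning genes had a median of 0.37 over 10 genes, of which Lhx2 passed (adjusted p = 0.0469; adjusted p = 0.315 with an estimated correlation). That list lost its call with chip as a random block (adjusted p = 0.0526), with the normal brain covariate (0.0797) and without any of 7 of the 14 tumours (up to 0.108), among other settings. Lhx2 lost its call without Type 1 replicate 2 (0.0574), and Aqp4 without Type 2 replicate 5 (0.0582).

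Markers of mature neurons moved with these groups. Their median difference was 0.91 over 13 genes, all positive, and Rbfox3 and Kcnc1 passed (camera adjusted p = 0.000702, and 0.411 with an estimated correlation). It was 0.64 without Type 1 replicate 1 and 1.42 without Type 2 replicate 6. The median was 1.95 in batch 1 and 0.03 in batch 2, where Rbfox3 and Kcnc1 differed by 1.31 and 1.32. In a type by batch test of this list by camera, chosen after seeing the results, the adjusted p was 0.00113 with the preset correlation. It was 0.773 with an estimated one, so a difference between the batches stays undecided. The medians of the astrocyte list were 1.30 and 0.68, those of the neuroblast list 0.97 and 0.61, those of the neural stem and progenitor list 0.18 and 0.77, those of the classical list 0.55 and 0.62, and those of the forebrain list 1.08 and 0.21.

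By camera with a preset correlation, 7 lists were higher in Type 2. Of 21 extracellular matrix genes, 6 were higher in Type 2 (Col6a1, Col6a2, Col18a1, Lamc1, Vcan and Acan) and 15 did not pass, with a median of -1.05 (adjusted p = 3.748e-07; adjusted p = 0.0979 with an estimated correlation). Col18a1, a basement membrane collagen, differed by -1.62 ± 0.30 (SE), and 11 genes passed when adjusted over the list alone. Of 13 mural and fibroblast genes, Rgs5, Col1a1, Col6a1 and Lum were higher in Type 2 (median -0.90; adjusted p = 0.0001415; adjusted p = 0.0979 with an estimated correlation). Of 13 endothelial genes, Vwf (-1.78 ± 0.26, SE) and Tie1 (-0.87) were higher in Type 2 and 11 did not pass (median -0.70; adjusted p = 0.000207; adjusted p = 0.152 with an estimated correlation). Of 21 genes of the human glioblastoma mesenchymal list, Anxa2, Tgfbi and Stat3 were higher in Type 2 (median -0.72; adjusted p = 0.000101; adjusted p = 0.236 with an estimated correlation). Of 21 oligodendrocyte progenitor genes, the transcription factor gene Sox10 (-1.79 ± 0.46, SE) and Erbb3 (at least 1.66-fold) were higher in Type 2 and 19 did not pass (median -0.60; adjusted p = 0.00161; adjusted p = 0.320 with an estimated correlation). Several of these calls lay near the threshold (adjusted p = 0.0408 for Sox10, 0.0492 for Col1a1, 0.0491 for Stat3 and 0.0483 for Col6a1), and with each tumour left out in turn Sox10 ranged from -1.98 to -1.36 and Col1a1 from -2.07 to -1.41. Of the 14 tumours, 12 ended the call of Sox10, 12 that of Col1a1, 11 that of Stat3, 10 that of Col6a1, 8 that of Tgfbi and 1 that of Anxa2 (Type 1 replicate 2, adjusted p = 0.0554).

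The 7 class II antigen presentation genes all had lower means in Type 1, with a median of -1.11 (adjusted p = 0.0007465; adjusted p = 0.315 with an estimated correlation), and H2-Ab1 alone passed, at -2.40 ± 0.49 (SE). Their medians were -0.54 in batch 1 and -1.85 in batch 2. The 10 class I genes had a median of -0.56 (adjusted p = 0.00777; adjusted p = 0.488 with an estimated correlation), with -0.05 in batch 1 and -1.22 in batch 2, and Psmb9 alone passed, a call that 11 of the 14 tumours ended when left out. The microglia and macrophage list had medians of 0.54 in batch 1 and -0.77 in batch 2. In the other lists higher in Type 2, the medians of batches 1 and 2 were -1.14 and -1.21 for extracellular matrix, -0.69 and -0.73 for mural and fibroblast, -0.52 and -0.77 for endothelial, -0.50 and -0.75 for mesenchymal and -0.49 and -0.68 for oligodendrocyte progenitor genes.

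**Figure D3:**
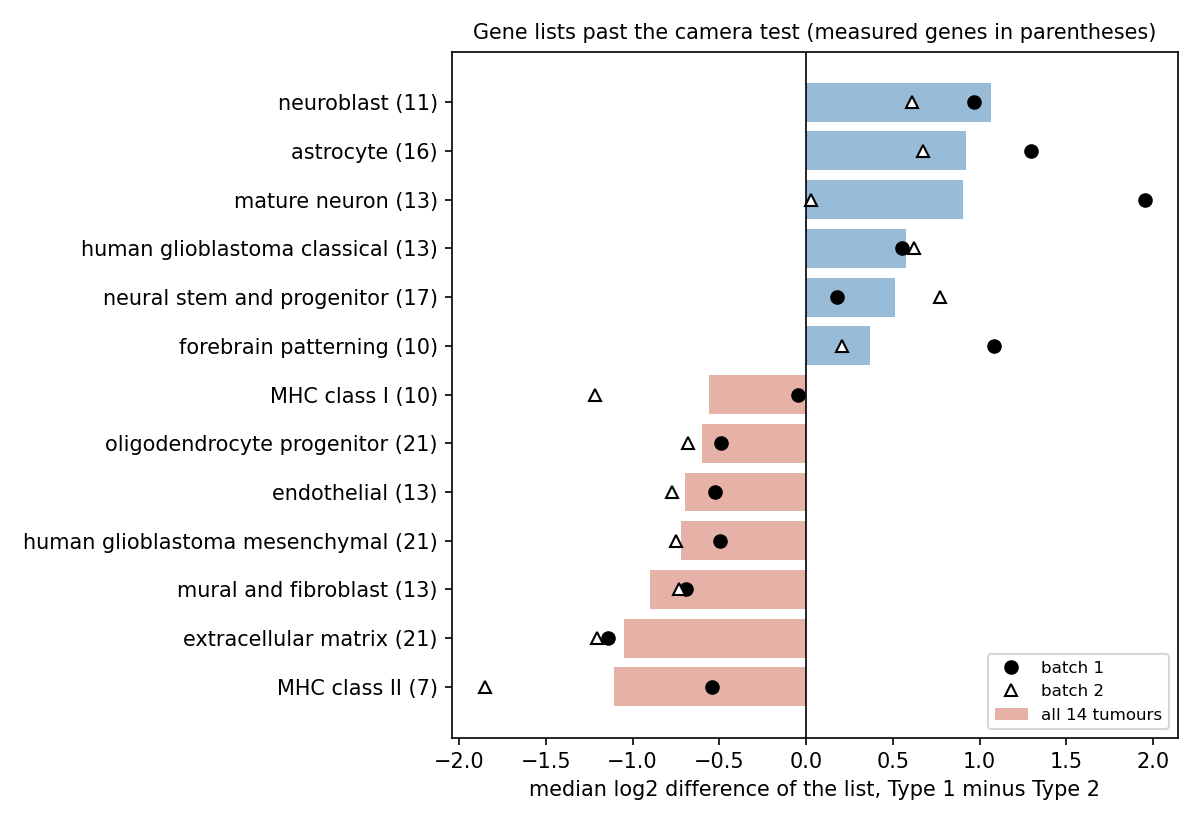
Median log2 difference (Type 1 minus Type 2, horizontal axis) of the 13 gene lists past the camera test, with bars for all 14 tumours, circles for batch 1 and triangles for batch 2. The mature neuron list lay at 1.95 in batch 1 and 0.03 in batch 2, and the class I list at -0.05 and -1.22.

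The remaining 18 tested lists did not pass. Their medians were -0.08 for myelinating oligodendrocyte genes, 0.02 for microglia and macrophage (mean -0.07; 0.54 in batch 1 and -0.77 in batch 2), 0.06 for ependymal and ciliated, 0.45 for choroid plexus (2.31 in batch 1 and -0.78 in batch 2; -0.50 without Type 1 replicate 1 and 1.00 without Type 2 replicate 5), -0.18 for cell cycle and 0.12 for the human glioblastoma proneural list. Medians were 0.08 for receptor tyrosine kinases, -0.39 for ERK pathway feedback targets, -0.07 for p53 targets, 0.32 for hindbrain and caudal patterning, 0.24 for Notch, 0.27 for Hedgehog and -0.04 for Wnt. They were -0.38 for hypoxia, which was called when any of 6 of the 14 tumours was left out, -0.14 for the interferon response, -0.09 for cholesterol synthesis, -0.31 for immediate early genes and -0.31 for strain-polymorphic genes. Within these lists, Cnp, Cldn11 and Ugt8a of myelin, Dnah11, Hey2, Phlda3, and the receptor genes Erbb2 and Erbb3 were higher in Type 2, whereas Egfr, Epha5, Ephb1, Dcx, Hoxa2 and Bbc3 were higher in Type 1. Left out in turn, 9 tumours ended the call of Hoxa2, 3 that of Cnp and 3 that of Dnah11. Too few genes were measured for a test of T and NK cell (3 genes, median 0.39), B cell (2, 0.01), red blood cell (2, 1.10) and sex-linked genes (4, 0.02).

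Of 11786 genes, 1258 differed between batches at adjusted p under 0.05 (limma), 737 higher and 521 lower in batch 2. That count was 4178 with median scaling and 0 with the authors' processed values, which called 551 genes between the types. The first principal component held 22.6% of the variance, of which type explained 71.7%, and the second held 14.8%, of which batch explained 67.8%. Arrays of the same type and batch correlated at a median r of 0.947 across genes, arrays of the same type in the other batch at 0.927, and arrays of other type in the same batch at 0.921.

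By a test that treats genes as independent, called genes were unevenly spread over the chromosomes. With tumours as the unit, a permutation test of the median of chromosome 2, chosen after seeing the results, gave an adjusted p of 0.114. On chromosome 2, 64 of 913 genes were called (7.01%), 56 of them higher in Type 1, among them Cbln4, Slc39a12, Slc1a2, Id1, Lhx2 and Entpd6 (Fisher's exact test, two-sided, adjusted p = 0.0152 over 20 chromosomes). The median difference of all genes of chromosome 2 was 0.26. None of the other chromosomes passed with all tumours and the main settings, and X had an adjusted p of 0.174. In batch 1 alone, and without Type 1 replicate 1, the 1 chromosome called was not chromosome 2. The call for chromosome 2 was lost with chip as a random block (adjusted p = 0.0503) and in batch 1 (0.0856) and batch 2 (0.840) alone. Of the 14 tumours left out in turn, 11 ended the call (adjusted p between 0.174 and 1), and it held without Type 2 replicate 2, Type 2 replicate 5 or Type 1 replicate 7.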

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

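Chosen only after the results were seen were the test of probe variants for Peg3 and Usp29, the test of myelin genes beside the mature neuron list, the fibroblast covariate with its test on Dct and Mcam, the type by batch test of gene lists, and the pigment, peripheral nerve, fibroblast and imprinted gene lists.

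The astrocyte, neuroblast and mature neuron lists were higher in Type 1 by camera with a preset correlation but not with an estimated one (adjusted p = 0.187, 0.0979 and 0.411 with an estimated correlation), and normal brain tissue in the samples might add such RNA. With the mean of the mature neuron and myelin lists as a covariate, the astrocyte median went from 0.92 to 0.73 with a camera adjusted p of 0.000111 at the preset correlation. That covariate joined a list higher in Type 1 (mature neuron, median 0.91) with 1 that was not (myelin, -0.08), so it may correct too little. Normal brain therefore stays open for the astrocyte list. The neuroblast median fell to 0.44 from 1.06 with an adjusted p of 0.00217, so normal brain stays open for that list. For the mature neuron list it also stays open, since the myelin list did not pass (adjusted p = 0.261) and grey matter holds little myelin. A difference between the tumour types themselves stays open for all 3 lists.

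Dct, Pmel, Dhh, Mcam and Cdh19, put together after their calls were seen, so that their median of -3.84 restates that choice, are known from pigment cells and peripheral glia, and cells from outside the tumour might bring them. The other melanocyte genes measured (4 of 9) had a median of 0.03 (0.0343) with 0 past the test (limma, 1 at unadjusted p under 0.05). Gpnmb was at -1.45 (limma adjusted p = 0.0837) and the other 3 lay near background, and Tyr, Tyrp1 and Mitf were detected on no array. Genes near background can show little, and Gpnmb, the bright gene, leaned to Type 2, so melanocytes stay open. Myelinating Schwann cell genes (6 of 9 measured) had a median of -0.58, 0 of them past the test (limma, 3 at unadjusted p under 0.05). Of those 3, Drp2 was higher in Type 1 (1.23 ± 0.36, SE, limma adjusted p = 0.0617). Ncmap (-1.72 ± 0.68, SE) and Pmp22 (-0.66 ± 0.29, SE) leaned to Type 2, so peripheral nerve stays open. With fibroblast genes as a covariate the median of the 5 genes was -3.17. Dct (-4.40 ± 0.49 to -3.17 ± 0.37, SE) and Mcam (-3.09 ± 0.33 to -2.97 ± 0.44, SE) kept their call. Pmel (-3.84 ± 0.53 to -3.30 ± 0.67, SE) and Dhh (-4.20 ± 0.70 to -3.22 ± 0.82, SE) lost it with larger SEs, and Cdh19 (-2.23 ± 0.55 to -1.09 ± 0.55, SE) lost it with a smaller difference. Of the fibroblast genes behind that covariate, Col1a1 and Col1a2 were detected on 0 of 7 Type 1 arrays. The covariate may therefore correct too little, and a kept call does not exclude this source. Fibroblasts or meninges stay open for Dct, Mcam, Pmel, Dhh and Cdh19. The origin of the tumours under the 2 drivers stays among the open explanations and was not tested. Other cell types, those of the endothelial and mural lists among them, were not tested as a source of the 5 genes either.

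Peg3 and Usp29, neighbours in an imprinted domain on chromosome 7, were both higher in Type 1, Peg3 having been picked after its values were seen. All 4 of their detected probes passed the test, which argues against a variant under 1 probe. Of 22 other imprinted genes measured, 0 passed by limma and 6 had an unadjusted p under 0.05, against 21.8% of all genes, with a median of 0.22. With 0 past the test, the one-sided exact binomial p was bound to be 1 and decides nothing. A smaller shared change of imprinted genes stays open. Of 55 other genes within 5 Mb, 2 passed (Fisher's exact test, one-sided, p = 0.73), so called genes were not shown to be more frequent there. A change of few genes of that segment, or one too small to be called, stays open. A narrower strain haplotype or a change of the domain itself may still account for the pair and was not tested.

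Other splits of the tumours, within batches for the types and within types for the batch term, were compared with the real one. Of 100 splits, the real one included, 1 gave as many genes as the real 547, and the highest other gave 6, so a random split is an unlikely source of the count of genes. As many gene lists as the real 13 came from 5 of 100 splits, with 14 at most, so chance is not excluded for the count of lists. For the batch term 1 of 100 splits gave as many as 1258 genes (highest other 1). Within batch 1 it was 1 of 35 splits (166 genes, highest other 1) and within batch 2 also 1 of 35 (123 genes, highest other 10). The real split is counted, so 1 of 35 is the lowest share possible and cannot exclude chance. Since no chip held both types, a chip effect would also set the real split apart from the others. The interaction called 0 genes (limma, 1931 at unadjusted p under 0.05), and since any split gives at least 0, the 100 of 100 that did so decide nothing (highest other 4). The correlation of 0.261 between batches was above the highest of the other splits, 0.245.

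Single tumours stood apart from the other 6 of their type in 20 of 218 groups of 7 values (9.17%), whereas chance gives about 1 in 20. In Type 1, replicate 3 was at 13.32 for Slc39a12 (others 9.777 to 11.14), 6.46 for Fbll1 (8.849 to 10.48), 7.536 for Elavl4 (8.811 to 9.438) and 12.12 for Otx1 (8.367 to 9.522). Type 1 replicate 7 was at 9.594 for Gata6 (4.629 to 6.41), replicate 1 at 7.205 for Gpr17 (11.08 to 13.6) and replicate 4 at 9.012 for Bbc3 (9.694 to 10.17). In Type 2, replicate 3 was at 6.1 for Egfr (7.719 to 8.763) and replicate 1 at 5.053 for Eya1 (8.403 to 9.013). Type 2 replicate 2 was at 5.492 for Lhx2 (4.73 to 5.033) and 8.552 for Zic1 (5.152 to 6.591). Type 2 replicate 4 was at 6.221 for Elavl3 (8.487 to 9.421), 4.936 for Kcnc1 (6.986 to 8.374) and 5.373 for H2-Aa (7.553 to 8.63). Type 2 replicate 7 was at 7.714 for Rgs5 (8.817 to 9.511) and 10.98 for Stat3 (11.64 to 12.04).

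Mean deviations of gene lists also set single tumours apart. Choroid plexus genes were at 4.401 in Type 1 replicate 1 (others -0.9249 to -0.4473) and 2.25 in Type 2 replicate 5 (-1.054 to 0.2442). Sex-linked genes were at -0.8213 in Type 1 replicate 7 (-0.04878 to 0.4013) and -1.145 in Type 2 replicate 4 (-0.2068 to 0.291). Outside the genes tested, 144 of 4977 detected probes with no gene name here passed the test, 90 higher in Type 1 and 54 higher in Type 2.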

How the results depend on the processing

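The covariates for Xist and for fibroblast genes, and leaving out the 2 tumours highest in choroid plexus genes, were chosen after seeing the data. The 547 genes became 166 (125 higher in Type 1, 41 in Type 2) in batch 1 alone and 123 (37 and 86) in batch 2 alone, which hold fewer tumours. They became 106 (49 and 57) without the 2 choroid plexus tumours, and 47 (34 and 13) with the fibroblast covariate. Stricter limits gave 67 (33 and 34) at adjusted p under 0.01 and 325 (158 and 167) at 2-fold or more. Leaving out each tumour gave 195 to 639 genes (99 to 304 higher in Type 1, 96 to 335 in Type 2), 12 to 14 lists, a correlation between batches of 0.184 to 0.305, 0 to 36 interaction genes, 867 to 1334 genes for the batch term and 0 to 2 chromosomes. The 36 came without Type 1 replicate 2. Of 57 named genes called, 51 kept their call with chip as a random block, 8 with the fibroblast covariate and 22 without the 2 choroid plexus tumours, and 0 turned direction. Cbln4, Dct, Egfr, Mcam and Usp29 kept their call in all 16 other settings.

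Of the 13 lists, 0 held with an estimated correlation (camera; 7 at unadjusted p under 0.05) and 9 by fry. In batch 1 alone 8 kept their call and in batch 2 alone 10, and 11 kept it with the fibroblast covariate and 11 without the 2 choroid plexus tumours. Forebrain, class I, class II, mature neuron, oligodendrocyte progenitor, neural stem and progenitor, mesenchymal and classical genes were the lists lost in 1 or more of these 4. Other lists were gained: myelin (camera adjusted p = 0.0238, median -0.34) and hindbrain (0.0493) genes with the normal brain covariate. The myelin genes are part of the normal brain covariate, so their call there decides nothing. Hypoxia genes were gained without the 2 choroid plexus tumours (0.0369), 3 lists in batch 1 alone and 3 with the fibroblast covariate. In batch 2 alone 15 lists were called, with 4 gained in their main direction and 1 gained after turning direction. The microglia list turned to -0.7716 in batch 2 alone and to -0.3452 without Type 1 replicate 3, where it passed its test. Over tumours left out, the microglia list ran from -0.3452 to 0.1153. The choroid plexus list, which did not pass, turned to -0.50 without Type 1 replicate 1, and the cause of these turns was not tested. The interaction called 2 genes with no background correction, 1 with the authors' values, 11 with no detection filter and 5 with a stricter filter. The batch term called 4178 genes with median scaling, 0 with the authors' values and 674 without the 2 choroid plexus tumours. Chromosome 2 was the 1 chromosome called with the main settings, and in batch 1 alone the 1 called was another. The count was 2 with the authors' values. It was 0 with no batch term, chip as a random block, batch 2 alone, median scaling, probe means, either added covariate, or without the 2 choroid plexus tumours. The correlation between batches was 0.552 over genes called in batch 1 and 0.758 over those called in batch 2. Causes of these shifts were not tested. No paired analysis was possible because replicate numbers follow accession order only. Dim probes limit the folds of genes near background.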

Other observations

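The test of chromosome 2 per tumour and the type by batch test of gene lists were chosen only after the results were seen.

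Xist, the RNA of the inactive X chromosome, was between 10.5 and 11.64 in Type 1 replicates 1, 4, 5 and 6 and Type 2 replicates 1, 2 and 5. Type 1 replicate 7 and Type 2 replicate 4 were low in Xist (4.516 and 4.534) and at 5.728 and 5.33 for the Y-linked gene Eif2s3y, against 8.165 to 9.153 in the other tumours low in Xist.

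Some gene lists differed in their type difference between batches by camera with a preset correlation. These were microglia and macrophage (adjusted p = 1.029e-06), mature neuron (0.00113), cell cycle, proneural and class I (each 0.0114), class II (0.019) and choroid plexus (0.0467) genes. With an estimated correlation, none of the 31 passed, the lowest adjusted p being 0.773.

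A copy gain of chromosome 2 in Type 1 tumours may raise many of its genes a little, and a loss in Type 2 tumours cannot be told apart from it here. The median of the chromosome's genes per tumour was 0.25 higher in Type 1, with an exact permutation p of 0.00571 over 1225 permutations within batches and an adjusted p of 0.114 over 20 chromosomes. As a deviation from the batch mean it was 0.12 ± 0.08 (SD, n = 7) in Type 1 and -0.12 ± 0.16 (SD, n = 7) in Type 2. Within Type 2 it ran from -0.347 in replicate 4 to 0.117 in replicate 2. Uncalled genes of chromosome 2 had medians of 0.241 in the part nearer the centromere (419 genes) and 0.224 in the rest (430 genes), against -0.0232 on other chromosomes (10372 genes). The adjusted p leaves both hypotheses undecided, since chromosome 2 was picked as the most extreme.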
